A study of Caenorhabditis elegans with 2 samples.

How the data were processed

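Chromatin immunoprecipitation and sequencing was done by the authors on sonicated chromatin of C. elegans strain OP696 with an anti-GFP antibody, in 2 biological replicates of mixed-stage embryos, per the labels. The 2 replicates form 1 group, taken from the replicate numbers in the labels. The deposited files are peak lists on the ce10 and ce11 builds. For each replicate and for the pooled replicates there is a relaxed list of peaks and background, called with a control and holding 30000 peaks, per the file headers and the values. The authors derived the IDR-thresholded list from the relaxed lists of both replicates and of the pool, per the file headers. The aligner, the peak caller, the IDR threshold and the scaling of the signal are not given in the sources used here.

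The signal of each peak is the authors' own deposited value. It was used here to rank and describe peaks within a list, to compare promoter with other peaks, and to compare the 2 replicate lists. The deposited −log10 q-value of each peak reached its maximum of 2.35 in 38.5% of IDR peaks on ce11 and was used only to break ties in the ranking. The deposited summit is given as a distance from the peak start. Depth is unknown, since the files hold no read counts. The p-values and intervals over peaks or genes cover counting error only, and peaks are not replicates.

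Coordinates were compared with Ensembl release 115 on WBcel235, the assembly also called ce11, and no peak lay past the end of a chromosome. All comparisons with genes and sequence used the ce11 lists, and the ce10 lists were compared only with each other. The 1423 nuclear IDR peaks entered the comparisons, and the 20 mitochondrial peaks are described apart. Peaks of 2 lists were matched where their overlap covered at least 50% of either peak, and the share given by chance came from 100 shuffles that kept widths and chromosomes. Summits were classed in the order promoter, first exon or 5' UTR, 3' UTR, other exon, intron, 500 bp downstream of a gene and intergenic. The 3' UTRs and the 500 bp downstream together form the class of 3' ends. The classes were compared with 10000 sets of random positions on the same chromosomes. Density on X against autosomes, and in the middle against the outer parts of chromosomes, was compared with 10000 random placements over the genome.

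A gene was a target where a summit lay from 1000 bp upstream to 500 bp downstream of its 5' end. A summit could make more than 1 gene a target, and the tests counted each gene apart. The p-values of lists whose members share summits therefore come out too small. Each of 41 gene lists was compared with all other protein-coding genes, or for RNA gene classes with all other genes, by Fisher's exact test. Adjusted p-values are Benjamini-Hochberg values over the lists, the location classes, the density comparisons or the words, with a threshold of 0.05. Words of 7 bases were counted within 50 bp of each summit and in flanks 200 to 300 bp away. Difference in signal by location was tested with 100000 resamples. Intervals of shares are exact Clopper-Pearson intervals at 95%. All tests were two-sided. The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

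Genes were named by rule. Nuclear IDR peaks matched in both replicates were taken in order of signal, each naming the protein-coding gene with the nearest 5' end if the summit lay in its promoter window, until 25 genes were named. M03D4.4, up to 4 members with the highest signal of each list past the threshold, and the members of lists with 4 or fewer targets were named as well. Genes named beyond these, the leading members of the homeobox, nuclear hormone receptor and cell cycle lists among them, were chosen after their values were seen. The gene lists, tests, naming rule and most alternatives were fixed before the data were examined. After that, 3 alternatives were added: leaving out peaks within 500 bp of any small RNA gene, leaving out peaks near tRNA or rRNA genes for density and for signal by location, and leaving out list members that the name patterns had taken in from other families. The last affected 11 homeobox, 3 C2H2 and 1 cytosolic ribosomal protein list members, and the lists were otherwise kept as fixed. Counts of peaks near small RNA genes, G and C content, and the places of single words were also described only after the peaks had been seen.

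The alternatives were the 711 strongest IDR peaks, the same number of top pooled peaks, each replicate alone with its 1423 strongest peaks, the ce10 lists, matches by 1 bp or by summits within 100 bp, a promoter window of 500 bp upstream, the nearest 5' end at any distance, a background of genes with a relaxed peak, low-ranked relaxed peaks as the expectation or as control windows, leaving out peaks near tRNA or rRNA genes, density per 1000 protein-coding genes, a window of 10 kb around M03D4.4, and words of 6 or 8 bases. The steps were tested on simulated data. Random summits gave p under 0.05 in 4.50% of 1200 location tests and 5.75% of 400 density tests, and random targets in 2.80% of 820 gene list tests. These random targets were drawn gene by gene, so the last rate does not cover lists whose neighbouring members share a summit. A planted excess of promoter summits and planted ribosomal protein targets were each called in 100% of 20 runs.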

Results

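Binding of M03D4.4, a predicted C2H2 zinc finger protein of Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing with an anti-GFP antibody. The strain, OP696, carries a transgene in which the protein ends in a GFP-FLAG tag. The chromatin came from mixed-stage embryos, 2 h after egg bleaching. The design had 1 group of 2 biological replicates, so peaks were described within that group and no conditions were compared. No list from another tagged protein was analysed here, so binding cannot be told apart from chromatin recovered whichever protein is tagged. The deposited list of peaks that passed the irreproducible discovery rate (IDR) threshold held 1443 peaks on the ce11 build, 1423 of them on the 6 nuclear chromosomes and 20 on the mitochondrial genome. On the older ce10 build the list held 1450 peaks, 1430 of them nuclear. The median peak width was 430 bp. The signal of the nuclear peaks ranged from 147 to 2198, with a median of 205. The files hold peaks and no read counts, so the sequencing depth of each replicate is unknown. Coordinates are 1-based on ce11, and signal values are the authors' own.

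The gene of the tagged protein, of which the transgene adds copies, was examined first. M03D4.4 (WBGene00019751, chromosome IV, 6121773 to 6127302, minus strand) had 0 IDR peaks within 20 kb on either side, where random windows of the same size held a mean of 0.65 (95th percentile 2). As few peaks were found in 57.5% of the random windows, so a count of 0 does not set this locus apart. The nearest IDR summit, at position 6097246, lay 24527 bp away with a signal of 261. The relaxed lists of the pool and of both replicates also held 0 peaks in the window, as did 3.27%, 1.89% and 1.75% of random windows over the genome and 7.26%, 3.34% and 2.51% of those within 1 Mb of the gene.

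The strongest peaks were found in both replicates. The strongest nuclear peak, 70 bp upstream of the snoRNA gene W03C9.9 on chromosome II (summit at position 11960828), had a signal of 1143 in replicate 1 and 1061 in replicate 2, and ranked first among the nuclear peaks of both. The promoter peak of rpl-3, a ribosomal protein gene, had 711 and 604, and that of ftt-2, which encodes a 14-3-3 protein, had 629 and 580. Of the 1423 nuclear IDR peaks, 1420 were matched in the longer list of replicate 1 (99.8%, 95% interval 99.39 to 99.96%) and 1421 in that of replicate 2 (99.86%, 99.49 to 99.98%). Randomly placed peaks of the same widths were matched at 12.3% in either list. The IDR list was derived from these same lists, so this share is not independent of them. Among the 1423 strongest nuclear peaks of each replicate taken alone, 1017 of replicate 1 were matched in replicate 2 (71.5%, 69.0 to 73.8%) and 1009 the other way (70.9%, 68.5 to 73.3%), against 0.595% and 0.645% of randomly placed peaks. Across the 1418 peaks found in both lists, log2 signal correlated with a Pearson r of 0.815 and a Spearman rho of 0.684. These correlations are across peaks, which are not independent replicates. The median log2 difference of replicate 2 from replicate 1 was -0.19, with an SD of 0.46 over peaks. The scaling of the signal is not given, so the size of this difference has no known meaning.

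**Figure D1:**
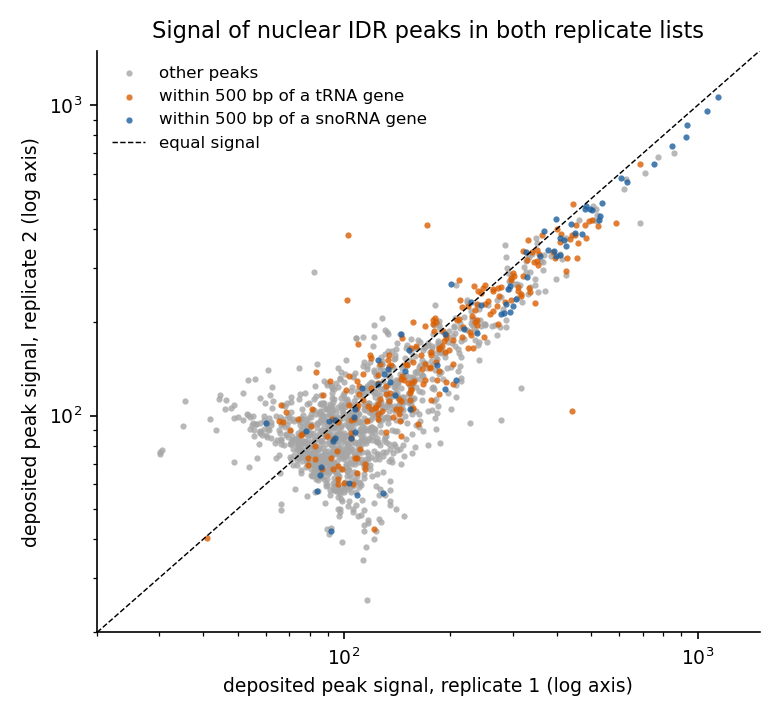
Deposited peak signal of the 1418 nuclear IDR peaks found in both replicate lists, replicate 1 on the x axis and replicate 2 on the y axis, both on log axes, with peaks within 500 bp of a tRNA gene in orange and of a snoRNA gene in blue. The strongest peak, at the snoRNA gene W03C9.9, lies at 1143 and 1061, and the Spearman rho across peaks is 0.684.

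Where the peaks lay relative to genes was asked next. Promoters, taken as 1000 bp upstream to 500 bp downstream of the 5' end of a protein-coding gene, held 714 of the 1423 summits (50.2%, 95% interval 47.5 to 52.8%), 1.97 times the 25.5% of random positions on the same chromosomes. Promoter summits lay at a median of 206 bp upstream of the 5' end, with quartiles at 383 and 86 bp upstream. The peak of idhg-1, an isocitrate dehydrogenase subunit gene, lay 63 bp upstream, and that of atx-2, the ataxin-2 gene, 64 bp upstream. Exons other than the first held 15 summits (1.05% against 16.8% of random positions), and introns held 326 (22.9% against 28.6%). Small RNA genes, that is tRNA, rRNA, snRNA, snoRNA and microRNA genes, lay within 500 bp of 128 of the 326 intron peaks (39.3%, 33.9 to 44.8%). The same held for 9 of the 15 other exon peaks (60%, 32.3 to 83.7%) and 36 of the 77 3' end peaks (46.8%, 35.3 to 58.5%). It held for 68 of the 282 intergenic peaks (24.1%), 100 of the 714 promoter peaks (14%, 11.5 to 16.8%) and 0 of 9 first exon or 5' UTR peaks. Without peaks near any small RNA gene other exons held 6 of 1082 summits, and their value fell from 0.0626-fold to 0.0328-fold. The excess in promoters and the deficits in other exons and introns each had a two-sided permutation p of 0.0001, the smallest that 10000 draws can give. First exons and 5' UTRs outside promoters held 9 summits (0.632% against 1.4%, two-sided permutation test, adjusted p = 0.0283). The call for first exons and 5' UTRs was lost without replicate 2 (0.549-fold), without peaks near tRNA or rRNA genes (0.535-fold) or near any small RNA gene (0.597-fold), and against low-ranked relaxed peaks (0.429-fold), and among the 711 strongest peaks the value fell to 0.101-fold. Intergenic sequence held 282 summits (19.8% against 21.7%, adjusted p = 0.102 in the two-sided permutation test) and 3' ends 77 (5.41% against 5.95%, adjusted p = 0.399). With a promoter window of 500 bp upstream the intergenic share was 1.05-fold, and 3' ends lay at 1.05-fold without replicate 1, 1.04-fold without replicate 2 and 1.02-fold among the 711 strongest peaks, none past the threshold. Intergenic summits were fewer among the 711 strongest peaks (0.758-fold) and more frequent than among low-ranked relaxed peaks (1.31-fold), and 3' ends passed the threshold without peaks near tRNA or rRNA genes (0.750-fold) or near any small RNA gene (0.640-fold).

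**Figure D2:**
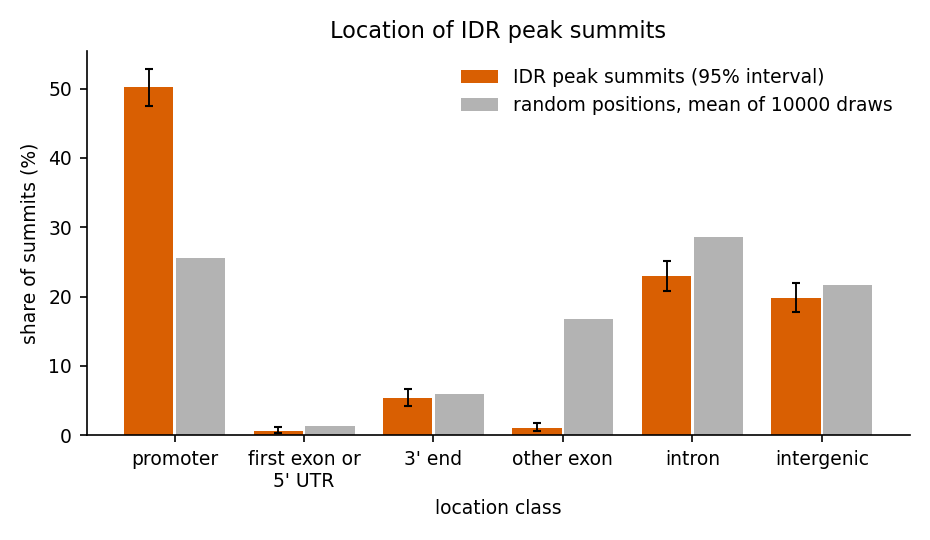
Share of the 1423 nuclear IDR summits in each of 6 location classes (orange, with 95% Clopper-Pearson intervals) beside the mean share of 10000 sets of random positions (grey). Promoters hold 50.2% of summits against 25.5% of random positions, and exons other than the first 1.05% against 16.8%.

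The 25 genes named from the strongest peaks of both replicates, each the protein-coding gene whose 5' end lay nearest a summit in its promoter window, came from the first 70 nuclear ranks. The genes whose peaks had no small RNA gene within 500 bp numbered 13. They were led by K12H4.5 (WBGene00019680, chromosome III, 8044487 to 8044780, plus strand), with a signal of 1458 (773 in replicate 1 and 683 in replicate 2). Next came rpl-3 (WBGene00004414, chromosome III, 3867854 to 3869587, plus strand) with 1317, ftt-2 (WBGene00001502, chromosome X, 11603708 to 11605419, minus strand) with 1210, and atx-2 (WBGene00000231, chromosome III, 10461389 to 10468051, plus strand) with 1155. The others of this kind were tasp-1, ears-2, T13C5.6, idhg-1, rpl-15, nmad-1, Y17G9B.5, dnj-29 and spat-3, with signals from 981 at tasp-1 down to 698 at spat-3. The peak assigned to Y17G9B.5 also lay 287 bp upstream of rpl-20, a ribosomal protein gene. The other 12 genes had a tRNA or snoRNA gene within 500 bp of the same summit. Of these, sre-23, a chemoreceptor family gene, had the highest signal, 1795, at a summit 615 bp upstream of it and 56 bp upstream of the snoRNA gene ZK265.10. The summit assigned to T02E1.2 (1399) lay near the snoRNA gene T02E1.9, and those of twk-5, F55A11.11, pdl-1 and wrt-3 also lay near snoRNA genes. The summits of C28G1.2, gcy-33, lev-9, col-85, F28H6.7 and egl-17, which encodes a fibroblast growth factor, lay near tRNA genes. A summit near 2 genes is assigned by distance alone, so these 12 names do not tell which gene the binding belongs to. The other 13 names follow the same rule, so they do not settle it either.

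Genes for tRNAs, snoRNAs, microRNAs and snRNAs carried peaks more often than other genes. None of 20 rRNA genes had a peak, but only 1 of them had even a relaxed peak in the same window, against 462 of 612 tRNA genes. The count of 0 therefore does not show less binding at rRNA genes. Of 612 tRNA genes, 260 had a peak (42.5%, 95% interval 38.5 to 46.5%) against 3.92% of other genes, an odds ratio of 18.1 (Fisher's exact test, two-sided, adjusted p = 6.51e-185). The other genes here include 15363 piRNA genes, of which 0.657% had a peak, against 6.26% of the 31527 genes that are not piRNA genes. The odds ratios in this paragraph would be lower against a background without piRNA genes, which was not run. Of 346 snoRNA genes, which encode guides for RNA modification, 85 had a peak (24.6%, 20.1 to 29.5%, odds ratio 7.30, exact test, adjusted p = 7.91e-38). MicroRNA genes had a peak in 34 of 261 cases (13.0%, odds ratio 3.27, exact test, adjusted p = 1.4e-07) and snRNA genes in 16 of 129 (12.4%, odds ratio 3.08, exact test, adjusted p = 0.000605). The strongest snoRNA peaks were at W03C9.9 (2198), at C51F7.3 and C51F7.4, which share 1 peak (2017), and at ZK265.10 (1795). The tRNA gene WBGene00000308 on chromosome X had a signal of 1339, WBGene00022955 on chromosome I 1004 and WBGene00022947 on chromosome X 939. The summit counted for the tRNA gene WBGene00023221 (1198) lay 931 bp upstream of it and near the snoRNA gene ZK994.7. Among microRNA genes cel-mir-51 had 1559, cel-mir-52 1090, cel-mir-354 418 and cel-mir-56 362. Among snRNA genes R07E5.16 had 744, followed by the spliced leader genes sls-2.4 (625), sls-2.2 (448) and sls-2.9 (414). Summits lay within 500 bp of a tRNA gene at 226 of the 1423 IDR peaks (15.9%, 14 to 17.9%), 24.7 times the share of random positions, and at 16.2% and 15.7% of the strongest peaks of replicates 1 and 2. Any small RNA gene was this close at 67 of the first 100 nuclear ranks (67.0%, 56.9 to 76.1%) and at 117 of the 923 ranks above 500 (12.7%, 10.6 to 15%). Summits near tRNA genes lay at a median of 16.5 bp downstream of the tRNA 5' end, and those near snoRNA genes 48 bp upstream. Against genes with a relaxed peak in the same window, the odds ratios fell to 8.62 for tRNA genes, 3.28 for snoRNA genes and 2.11 for microRNA genes, and among the 711 strongest peaks that of microRNA genes was 2.16, all still past the threshold.

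Among the coding lists tested, genes of translation, protein folding, chromatin and respiration carried peaks more often than other genes. A peak lay in the promoter window of 936 of 19973 protein-coding genes (4.69%). It lay in that of 32 of 83 cytosolic ribosomal protein genes (38.6%, 95% interval 28.1 to 49.9%, odds ratio 13.2, Fisher's exact test, two-sided, adjusted p = 1.76e-20), with rpl-3 (1317), rpl-15 (935), rpl-20 (714) and rpl-35 (624) at the top. Translation factor genes had 12 of 40 (30%, 16.6 to 46.5%, odds ratio 8.82, exact test, adjusted p = 8.88e-07). They were led by eif-3.C (663), an initiation factor 3 subunit gene, and followed by iff-2 (380), eef-1A.1 (294), an elongation factor gene, and eif-2Bgamma (258), the last 2 at summits near a microRNA and an snRNA gene. Heat shock protein and chaperonin genes had 15 of 59 (25.4%, 15 to 38.4%, odds ratio 7.03, exact test, adjusted p = 3.48e-07), among them dnj-29 (711), the mitochondrial chaperonin gene hsp-60 (565), hsp-1 (553) and dnj-9 (338). Genes of endoplasmic reticulum stress had 8 of 23 (34.8%, 16.4 to 57.3%, odds ratio 10.9, exact test, adjusted p = 2.20e-05), led by pdi-2 (292), hsp-3 (284), atf-6 (283) and enpl-1 (248). Chromatin regulator genes had 12 of 50 (24.0%, 13.1 to 38.2%, odds ratio 6.49, exact test, adjusted p = 1.0e-05), with cbp-1 (643), the CBP/p300 acetyltransferase gene, swsn-3 (506), lin-53 (350) and chd-7 (317). Oxidative phosphorylation genes had 9 of 40 (22.5%, 10.8 to 38.5%, odds ratio 5.95, exact test, adjusted p = 0.000264), with the cytochrome c oxidase genes cox-5B (589), cox-6A (345) and cox-5A (310) and the cytochrome c1 gene cyc-1 (334), the cox-6A summit lying near an snRNA gene. Against genes with a relaxed peak in the same window, these 6 odds ratios fell to 5.49, 3.95, 4.36, 4.81, 3.1 and 2.95, in the order given. With the nearest 5' end at any distance taken as the target, the first 5 fell to 4.47, 4.99, 3.83, 5.27 and 3.74, all still past the threshold.

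The 4 other coding lists past the threshold lost that call under at least 1 alternative. Histone genes had 15 of 72 (20.8%, 95% interval 12.2 to 32.0%, odds ratio 5.42, Fisher's exact test, two-sided, adjusted p = 4.44e-06). The histone genes his-67 and his-68 shared 1 peak (659), and his-61 and his-62 another (444). The test counts each gene apart, so shared peaks make its p-value too small and the interval too narrow. With the nearest 5' end as the target, where each summit counts for 1 gene, 10 of 72 histone genes were targets. Muscle genes had 7 of 30 (23.3%, 9.93 to 42.3%, odds ratio 6.23, exact test, adjusted p = 0.00112), with unc-60 (229), a cofilin gene, mlc-2 (213.6), act-1 (195) and unc-112 (193). Spliceosome and SR protein genes had 7 of 36 (19.4%, 8.19 to 36.0%, odds ratio 4.94, exact test, adjusted p = 0.00315), with snr-1 (480), prp-19 (414), snr-4 (218, near an snRNA gene) and rsp-1 (184). Mitochondrial ribosomal protein genes had 8 of 70 (11.4%, 5.07 to 21.3%, odds ratio 2.64, exact test, adjusted p = 0.0353), with mrps-28 (1198) and mrpl-23 (666), both at summits near snoRNA genes, and mrpl-45 (309) and mrpl-12 (255). The histone call was lost with the nearest 5' end as the target (odds ratio 2.41), and the muscle call among the 711 strongest peaks (2.69) and against genes with a relaxed peak (2.80). The spliceosome call was lost in those same 3 settings (1.86, 3.43 and 2.19, in the order given), and the mitochondrial ribosomal protein call in 6 of 8 settings (1.44 to 2.40), among them without replicate 1 (2.40) and without replicate 2 (2.34), while among the 711 strongest peaks its odds ratio was 4.22.

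**Figure D3:**
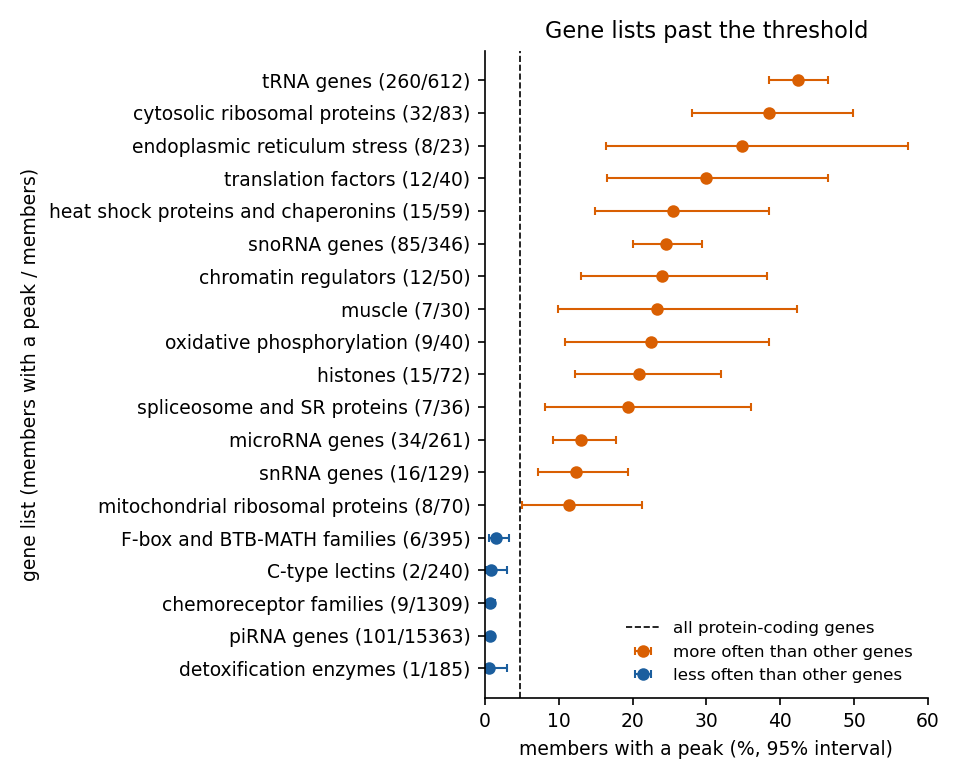
Share of members with a peak (x axis, %, with 95% Clopper-Pearson intervals) for the 19 of 41 gene lists past the threshold, those with more targets in orange and those with fewer in blue; the dashed line marks all protein-coding genes at 4.69%. The tRNA genes lie at 42.5% and cytosolic ribosomal protein genes at 38.6%, while chemoreceptor families lie at 0.688%.

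Chemoreceptor, F-box, lectin, detoxification and piRNA genes carried peaks less often than other genes. Chemoreceptor families had a peak at 9 of 1309 genes (0.688%, 95% interval 0.315 to 1.3%, odds ratio 0.132, Fisher's exact test, two-sided, adjusted p = 7.82e-17), the strongest at sre-23 (1795), sri-5 (577), sre-1 (559) and srh-16 (368). The piRNA genes had 101 of 15363 (0.657%, odds ratio 0.0991, exact test, adjusted p = 2.12e-221), the strongest at 21ur-13979 (954), near a snoRNA gene. The next 3, 21ur-5229, 21ur-356 and 21ur-11359, shared 1 peak (517) near a tRNA gene. Fisher's test counts each gene of these lists apart and does not allow for chromosome. Where neighbouring genes share a peak or its absence, the p-values in this paragraph come out too small. F-box and BTB-MATH families had 6 of 395 (1.52%, odds ratio 0.309, exact test, adjusted p = 0.00284), led by fbxb-85 (476), math-33 (453), fbxc-44 (428) and fbxb-58 (296). C-type lectin genes had 2 of 240, clec-53 (439) and clec-126 (307, near tRNA genes), with an odds ratio of 0.169 (exact test, adjusted p = 0.00416). Without replicate 2 the F-box and BTB-MATH count was 3 of 395 (odds ratio 0.157), still past the threshold. Detoxification enzyme genes had 1 of 185, the glutathione S-transferase gene gst-27 (609), with an odds ratio of 0.110 (exact test, adjusted p = 0.00568), at a summit near the snoRNA gene Y53F4B.48. The calls for F-box, lectin and detoxification genes were lost among the 711 strongest peaks (odds ratios 0.379, 0.313 and 0.203) and against genes with a relaxed peak (0.398, 0.255 and 0.298). The last of these backgrounds moved chemoreceptor families to 0.388 and piRNA genes to 0.502, both still past the threshold.

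The remaining 22 lists did not pass the threshold, among them most cell type markers and transcription factor families. No peak lay at any of 26 intestine, 15 pharynx, 39 basic helix-loop-helix, 21 T-box, 12 GATA, 20 forkhead and Sox, 24 Notch pathway or 20 rRNA genes. The upper 95% limits of these shares lay between 9.03% for basic helix-loop-helix genes and 26.5% for GATA genes, so a share like the 4.69% of all coding genes was not excluded. With either replicate left out 1 of 39 basic helix-loop-helix genes had a peak (odds ratio 0.564 without replicate 1 and 0.550 without replicate 2). Neuron genes had 4 of 40 (syd-2, unc-70, aex-3 and unc-10), germline and P granule genes 4 of 42 (mex-1, spn-4, xnd-1 and cgh-1), cilia genes 2 of 37 (daf-19 and dyf-3) and epidermis genes 1 of 35 (hmp-1). C2H2 zinc finger genes had 2 of 72 (ztf-13 and ztf-9), homeobox genes 5 of 110, led by ceh-20 (218), and nuclear hormone receptor genes 6 of 274, led by nhr-255 (593), near a tRNA gene. Collagen genes had 3 of 156 (col-85, col-185 and col-54), all near tRNA genes. Proteasome genes had 4 of 33 (rpn-7, rpn-11, rpn-3 and rpn-13) and V-ATPase genes 3 of 20 (vha-1, vha-9 and vha-13). Without replicate 2 the odds ratio of V-ATPase genes moved from 3.6 to 1.1 (1 of 20), that of neuron genes from 2.27 to 0.536 and that of epidermis genes from 0.598 to 1.27, and without replicate 1 that of germline and P granule genes from 2.15 to 1.07 (2 of 42), that of C2H2 genes from 0.580 to 0.933 and that of forkhead and Sox genes from 0 to 1.13, none past the threshold. Small RNA pathway genes had 3 of 38 (alg-5, nrde-2 and rde-10) and lincRNA genes 6 of 194. Cell cycle genes had 6 of 53 (odds ratio 2.61, Fisher's exact test, two-sided, adjusted p = 0.0754), led by lin-35 (300), the retinoblastoma gene. Wnt pathway genes had 4 of 30, mom-1 (797, at the summit near a tRNA gene that also named lev-9), mig-5 (245), mig-1 (194) and cfz-2 (169), with an odds ratio of 3.14 (exact test, adjusted p = 0.0930), and 3 of 30 without peaks near tRNA or rRNA genes (odds ratio 2.44). Wnt, cell cycle, neuron, proteasome and collagen genes passed the threshold in 1 or 2 alternatives each, Wnt genes without replicate 1 (odds ratio 4.31) and with the nearest 5' end (4.55), neuron genes with the nearest 5' end (4.34), cell cycle genes with 500 bp upstream (3.41) and without peaks near small RNA genes (3.0), and proteasome genes without replicate 2 (3.75). Without peaks near tRNA genes no collagen gene had a peak, which was past the threshold (exact test, adjusted p = 0.00544).

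The X chromosome held the most peaks per Mb. It carried 351 peaks, 19.8 per Mb, against 17.4 on chromosome III, 17.2 on I, 12.8 on II, 11.4 on IV and 8.46 on V. The X chromosome exceeded the autosomes together, at 13.0 per Mb, by a ratio of 1.53 (95% interval 1.35 to 1.72, two-sided permutation p = 0.0001, the smallest that 10000 draws can give). The tRNA genes were concentrated there, with 276 of 612 on X (45.1%), and snoRNA genes were not, with 33 of 346 (9.54%), while X made up 17.7% of the nuclear genome. Without peaks near tRNA or rRNA genes the ratio was 1.27 (1.1 to 1.46, two-sided permutation test, adjusted p = 0.00240), and X, at 14.4 per Mb, then lay below chromosomes I (15.5) and III (15.4). Without peaks near any small RNA gene the ratio was 1.41 (1.22 to 1.62), with X at 14.2 per Mb, III at 13.9 and I at 13.7, and per 1000 protein-coding genes X held 128.5 peaks against 90.9 on III. The middle of each chromosome, the central of 3 equal parts, held 14.9 peaks per Mb against 13.8 in the outer parts, a ratio of 1.08 (0.964 to 1.2, two-sided permutation p = 0.180). That ratio passed the threshold among the 711 strongest peaks (1.18) and, in the other direction, per 1000 protein-coding genes (0.887).

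**Figure D4:**
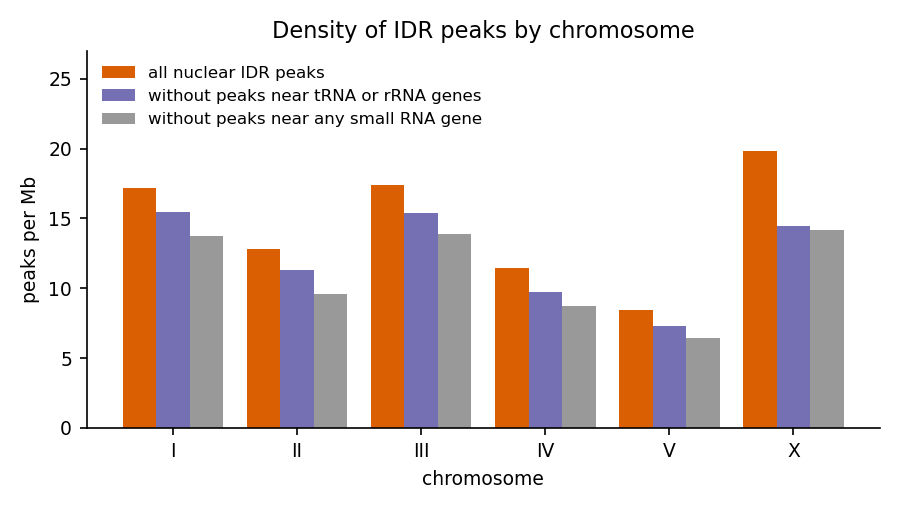
Peaks per Mb (y axis) on each nuclear chromosome (x axis) for all nuclear IDR peaks (orange), without those near tRNA or rRNA genes (purple) and without those near any small RNA gene (grey). The X chromosome lies at 19.8 per Mb with all peaks and at 14.4 without those near tRNA or rRNA genes, when chromosomes I and III lie at 15.5 and 15.4.

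Sequence at the summits was richer in G and C than around them, and many short words were more frequent there. The 100 bp at the summits had 49.9% G and C, against 37.1% in the flanks of the same peaks, 39.1% at low-ranked relaxed peaks and 35.4% in the nuclear genome. Of 8192 words of 7 bases, counted on either strand, 1355 were more frequent and 992 less frequent at summits than in the flanks (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted). The test pooled all windows and did not use the pairing of each summit with its own flanks. The word GGTTCGA, part of the B box of tRNA genes, was in 107 summit windows (7.52% against 0.738% of flanks, 10.2-fold, exact test, adjusted p = 5.25e-29), and 81 of them (75.7%) lay within 500 bp of a tRNA gene. TGCGCCA was in 80 windows (5.62% against 0.527%, 10.7-fold), 53 of them promoters and 21 near tRNA genes. AGTGCGC was in 71 windows (4.99% against 0.562%, 8.88-fold), 54 of them promoters and 1 near a tRNA gene. Repeats of CT and of CA were also frequent, with CTCTCTC in 156 windows (11.0% against 2.95%) and CACACAC in 147 (10.3% against 2.81%), 67 and 64 of them promoters. Words of A and T were less frequent at summits, AAAAATT for example in 5.83% of windows against 18.8% of flanks. Without peaks near tRNA or rRNA genes the excess of GGTTCGA fell to 4.0-fold, and without peaks near any small RNA gene to 3.33-fold, while that of AGTGCGC rose to 13.6-fold. Among the 711 strongest peaks GGTTCGA reached 16.4-fold and TGCGCCA 31-fold. Windows at low-ranked relaxed peaks as the control gave 801 more frequent and 596 less frequent words, with GGTTCGA at 6.69-fold, AGTGCGC at 14.2-fold, CTCTCTC at 5.78-fold (3.71-fold against flanks) and CACACAC at 6.13-fold (3.68-fold against flanks), and all of these excesses were past the threshold. Some of these folds rest on few control windows. TGCGCCA was in 4 flank windows of the 711 strongest peaks, and AGTGCGC in 10 flank windows without peaks near any small RNA gene. At low-ranked relaxed peaks AGTGCGC was in 5 windows. The words were compared with flanks of lower G and C content and not with windows of equal composition.

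**Figure D5:**
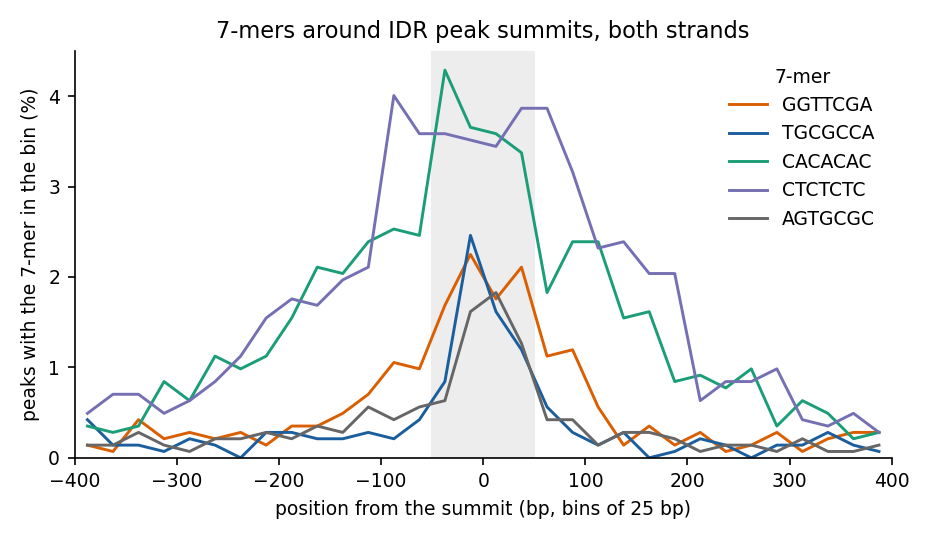
Share of the 1423 nuclear IDR peaks with each of 5 words of 7 bases, on either strand, in bins of 25 bp (y axis, %) by distance from the summit (x axis, bp), the grey band marking the window tested. TGCGCCA reaches 2.46% and GGTTCGA 2.25% of peaks in the bin next to the summit, while CTCTCTC and CACACAC reach 4.01% and 4.29% over a wider span.

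Promoter peaks and other peaks differed little in signal. The 714 promoter peaks, such as those of rpl-3 and ftt-2, had a median signal of 211, and the 709 others, such as those at W03C9.9 and C51F7.3, a median of 201. The difference of the medians was 0.07 on the log2 scale (two-sided permutation test with 100000 resamples, p = 0.0620). The difference passed the threshold in replicate 2 alone (0.11) and in replicate 1 alone (0.13), without peaks near tRNA or rRNA genes (0.15) and without peaks near any small RNA gene (0.18), while among the 711 strongest peaks it was -0.11 (permutation p = 0.101).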

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

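The mitochondrial counts were made only after these peaks had been seen, and no tests of an explanation were run. The mitochondrial genome lies outside the comparisons of nuclear peaks, and it held 20 IDR peaks; no control list was analysed here and no expected number was measured. They covered 8436 of 13794 bp (61.2%) and had signals from 292 to 5714 with a median of 2034, and all of the 10 strongest peaks of the IDR list were among them. Replicate 1 had 22 mitochondrial peaks and replicate 2 had 15 in their relaxed lists. No biological explanation was tested, since the design has 1 group.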

How the results depend on the processing

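Leaving out peaks near any small RNA gene, leaving out those near tRNA or rRNA genes for density and signal by location, and leaving out list members of other families were tests chosen after the data were seen. The same number of top pooled peaks was the IDR list itself (100% of 1423 peaks), so that alternative tested nothing and is not counted here. Of the values that answer a comparison, 88 kept their direction and side of the threshold or moved little, 14 moved, 8 newly passed the threshold, 4 lost it and 10 changed direction. Of the other values, that is single lists, single words and, on ce10, the median signal and the peak number of each chromosome, 331 kept theirs, 18 lost the threshold, 8 newly passed it and 20 changed direction. The promoter excess and the X to autosome ratio passed the threshold in every alternative run for them, and 8 of 19 called lists did. The tRNA, snoRNA, snRNA and microRNA lists are not among the 8. They kept their call except where peaks near those same genes were left out, an outcome fixed by that removal.

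IDR peaks matched in replicate 2 rose to 100% with an overlap of 1 bp. With summits within 100 bp the matched shares were 97.9% and 96.9% in the replicate lists and 65.1% and 65.1% between the strongest peaks, by a stricter match. Words of 6 bases gave 679 more frequent and 516 less frequent, since fewer such words exist. Low-ranked relaxed peaks as control windows gave 801 and 596. The 711 strongest peaks gave 628 less frequent words and 2 lists with fewer targets, an intergenic share of 0.758-fold and a ratio of the middle to the outer parts of 1.18. The background of genes with a relaxed peak also left 2 lists with fewer targets. The nearest 5' end gave 9 lists with more targets, in part because RNA gene lists could not be tested there. With 1 replicate left out the signal difference was 0.11 to 0.13 and first exons and 5' UTRs lay at 0.501 to 0.549-fold. Without peaks near tRNA or rRNA genes first exons and 5' UTRs lay at 0.535, 3' ends at 0.750 and the signal difference at 0.15. Without peaks near any small RNA gene these were 0.597, 0.640 and 0.18, and 8 lists had fewer targets. The odds ratio of tRNA genes fell to 0.143 and 0.114 in these 2 settings, and in the second that of snoRNA genes to 0.937, snRNA genes to 0 and microRNA genes to 0.134, because the peaks at those genes were removed. Against low-ranked relaxed peaks first exons and 5' UTRs lay at 0.429-fold and intergenic summits at 1.31-fold, and the ratio of the middle to the outer parts per 1000 protein-coding genes was 0.887. With a promoter window of 500 bp upstream intergenic summits lay at 1.05-fold. Without 1 replicate 3' ends lay at 1.04 to 1.05-fold, and among the 711 strongest peaks at 1.02-fold, with a signal difference of -0.11.

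Odds ratios of lists not past the threshold that crossed 1 stayed short of it. Among the 711 strongest peaks they were 0 for V-ATPase, 0.963 for neuron and 1.0004 for lincRNA genes. With replicate 1 or replicate 2 left out they were 3.08 and 0.536 for neuron genes, 1.13 and 0 for forkhead and Sox genes, and 0 and 1.27 for epidermis genes. Homeobox genes had 1.04 without peaks near tRNA or rRNA genes, 1.11 without peaks near any small RNA gene and 1.49 with the nearest 5' end. That last setting gave 1.24 for basic helix-loop-helix, 2.98 for GATA, 2.41 for C2H2, 2.49 for epidermis, 1.35 for Notch and 0.402 for small RNA pathway genes. With 500 bp upstream the values were 0.647 for germline and P granule and 0.717 for small RNA pathway genes, and against genes with a relaxed peak 0.956 for cilia genes. Where no reason is given the cause was not tested. Depth is unknown and its effect could not be examined.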

Other observations

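The comparisons of promoters between divergent genes, of snoRNA genes on X, of single-copy with repeated tRNA genes, of ribosomal protein genes as a sign of recovered chromatin, of the X ratio without peaks near tRNA genes and of relaxed peaks around M03D4.4 were tests chosen after the result was seen. Leaving out peaks near any small RNA gene was also added after the data were seen, and what it should show for the X ratio was written before that value was known. Of the 714 promoter peaks, 221 lay in the windows of genes on opposite strands (31.0%, 95% interval 27.6 to 34.5%), against 10.7% of random promoter positions (exact binomial test, two-sided, p = 1.22e-48). Promoter summits lay at a median of 206 bp upstream of the 5' end. The part of the difference that comes from this distance was not separated, so no preference for divergent promoters follows. On the X chromosome 1 of 33 snoRNA genes had a peak (3.03%), against 84 of 313 on the autosomes (26.8%, Fisher's exact test, two-sided, p = 0.00110). The tRNA genes had a peak as often on X (43.1%) as on the autosomes (42%, exact test, two-sided, p = 0.805), and a p of this size does not show that the shares are equal.

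Peaks at tRNA genes could come from reads shared between identical copies. Of the 140 tRNA genes whose exact sequence occurs once in the genome, 41 had a peak (29.3%, 95% interval 21.9 to 37.6%). Of the 102 among them with no repeated tRNA gene close by, 30 had a peak (29.4%, 20.8 to 39.3%). Both shares lay above the 4.69% of protein-coding genes, which argues against copies identical over the whole gene as the only cause. Genes whose sequences match only in part were not examined, so reads shared between those stay open, even as the whole cause. Repeated tRNA genes had a peak more often, 219 of 472 (46.4%, exact test, two-sided, p = 0.000308), so a part from identical copies stays open as well. Chromatin recovered whichever protein is tagged cannot be told apart from binding by M03D4.4, since cytosolic ribosomal protein genes also had peaks in excess (odds ratio 13.2) and no list from another tagged protein was analysed here. No biological explanation was tested.

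The higher density on X may come from the tRNA genes concentrated there. Without peaks near tRNA or rRNA genes the ratio was 1.27 (95% interval 1.1 to 1.46), and without peaks near any small RNA gene 1.41 (1.22 to 1.62), both above 1. The intervals cover counting error only, and the autosomes differed among themselves. They ran from 7.31 per Mb on V to 15.5 on I without peaks near tRNA or rRNA genes, and X lay within that range. Leaving out peaks near any small RNA gene also removed peaks at snoRNA genes, which lay mostly on the autosomes. Neither ratio therefore decides whether these genes are the whole cause or, given the fall from 1.53, a part of it. Without peaks near tRNA or rRNA genes X (14.4 per Mb) lay below I and III (15.5 and 15.4), and without peaks near any small RNA gene above them (14.2 against 13.7 and 13.9). No biological explanation was tested.

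Extra copies of M03D4.4 in the transgene could add peaks around the gene, but 0 IDR peaks lay within 20 kb, not above the 95th percentile of 2 in random windows, which does not exclude it, since copies in the control, whose strain is not given in the sources used here, would cancel. The relaxed lists of the pool and of both replicates also held 0 peaks there, against a mean of 13.6 pooled peaks in random windows and of 7.08 in windows within 1 Mb. As few pooled peaks lay in 3.27% of random windows of this size, in 7.26% of those within 1 Mb and in 9.53% of random windows with 10 kb on either side. The replicate lists, with 1.89% and 1.75% of random windows of 20 kb and 3.34% and 2.51% of those within 1 Mb, go against chance spacing, but with 10 kb they gave 6.82% and 5.98%, so it is left open. Reads from transgene copies in the control library might also leave such a gap, and with 0 peaks in either replicate list this cannot be told apart from chance, and no biological explanation was tested.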
